A study of Homo sapiens with 4 samples.

How the data were processed

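RNA was measured in 4 libraries of BEAS-2B cells, 2 without and 2 with 5 µM cadmium chloride for 72 h. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a TruSeq RNA kit. The submitters' processing notes name STAR 2.4, DESeq2 and DESeq and the build hg19, without giving the role of each. The counter, the annotation release and the use of strand are not given in the sources used here. The authors deposited, per the file headers and the values, whole-number counts of reads per RefSeq gene for each library, not normalized. The deposited tables also hold RPKM for each library, per the file headers. The authors' deposited comparison table holds the mean RPKM of each group, a log ratio, a p-value and an adjusted p-value. The log ratio in the authors' table is read as log2, since the log2 ratio of mean RPKM follows it with a slope of 1.11 over 1781 genes above 50 RPKM in control. Its values for genes with few reads are smaller than the log2 RPKM ratio. The adjusted p-value of the authors' table matches a Benjamini-Hochberg adjustment over 12807 genes and is 1 for the other 12604. Gene rows were joined by RefSeq identifier, because 4 symbols (MARC1, MARC2, MARCH1 and MARCH2) were exchanged between tables. No mitochondrially encoded gene has a row, so that list was not analysed here.

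The main comparison used the counts as deposited with R 4.3.3 and edgeR 4.0.16. Low-count genes were removed with filterByExpr, libraries were scaled with TMM, and a model with the group alone was fitted with the robust quasi-likelihood test (glmQLFit and glmQLFTest). Adjusted p-values are Benjamini-Hochberg values over 13663 genes with a threshold of 0.05, and are edgeR's wherever no other tool is named. Levels are CPM with TMM factors, given as mean ± SD over 2 libraries. The SE of a log2 fold change was derived from the F statistic. For genes with 0 reads in both controls a lower bound against 3 reads over the control group replaces the fold. Of 35 gene lists fixed in advance, 30 had at least 5 tested genes and were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry (limma 3.58.1). None of the 15 lists that passed with the preset correlation held with an estimated one. The named genes were SNAI1, CDH1, VIM, CDH2, FN1, NFYC and MIR30E, the 12 largest rises and 12 largest falls, and members of each list. The largest changes were taken among genes with adjusted p under 0.05, a mean of at least 5 CPM and both cadmium libraries on the same side of both controls. From each list up to 4 passing members with the largest change were taken, or the 2 with the smallest p where none passed, and the largest passing change against the list. Not all of these are printed, and some genes that the rule names are not reported here. The design, the lists, this rule and most alternatives were fixed before the data were examined.

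The 3' UTR sequences came from GENCODE v29 transcripts, a GRCh38 annotation used for sequence, length and GC content only. A 3' UTR was found for 12499 of the tested genes, among them 12479 of the 12575 coding genes (99.2%). The design had foreseen 1000 shuffled control words for the miR-30 site. The site has fewer distinct rearrangements, so all without a miR-30 7-mer and with sites in at least 50 UTRs were used, 827 for the main test.

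The procedure was tested on simulated counts for the same 13663 genes, with the library sizes and gene dispersions of the data, 5 draws and 200 changed genes per draw. Of genes changed by 2 on the log2 scale, 96.8% were recovered for rises and 91.6% for falls. For changes of 1 these shares were 80.8% and 71.2%. With each gene's own dispersion 14.2% of the calls were false, and with the dispersion set to its trend 4.63% were. The excess came with the spread of gene dispersions around their trend. The number of libraries per group was not varied, so its part in the excess was not tested. With no gene changed, 6.8 genes per draw were called. Camera called all 5 lists of 20 genes shifted by 0.5 and 0 of 145 unshifted lists. The simulated genes were drawn independently. These shares therefore do not cover lists whose members vary together, such as interferon-stimulated genes (estimated correlation 0.97). With an estimated correlation, and with fry, 0 of the 5 shifted lists were called, so these tests had little power in this design. In a test of the seed-site procedure a shift of 0.1 was found in 10 of 10 draws and no shift in 0 of 10. Fold changes were permuted over genes there, which removed any link with 3' UTR sequence. In the data the control words had a median difference of 0.046, so the draws do not give the power or false rate there.

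Alternatives were a replicate block, DESeq2 size factors, scaling by library size alone, no filter, a stricter filter of 5 CPM in 2 libraries, leaving out each library, DESeq2 1.42.0, limma-voom, an adjusted p of 0.01 and a tested fold of 1.5. Further ones were added after the data were seen: level-dependent scaling, thinning to the shallowest library, a crossed block, and leaving out read-through models. With 3 libraries left, the lone library of a group is assumed to vary like the other group. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used for the summaries.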

Results

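The data were gene-level read counts from BEAS-2B cells, an established line of human bronchial epithelial cells, grown for 72 h without added metal or with 5 µM cadmium chloride. There were 2 control and 2 cadmium libraries. Reads assigned to genes numbered 26529403 and 8609243 in control replicates 1 and 2, and 29937242 and 15537382 in cadmium replicates 1 and 2. At least 1 read was counted for 16520 and 15313 genes in the controls and for 17227 and 16378 genes in the cadmium libraries, of 25411 genes in the tables. Levels are given in CPM, read counts scaled to library size with TMM factors. In control replicate 2, the shallowest library, 3 reads corresponded to 0.356 CPM, against 0.115 CPM in control replicate 1. Such floors and the counting intervals cover counting error only. Libraries of the same group differed by more than sampling noise, with a chi-square per gene of 11.8 between the controls and 7.72 between the cadmium libraries. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. The labels put both controls under experiment 1 and both cadmium libraries under experiment 2. If these were separate experiments, experiment and treatment cannot be told apart.

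The comparison asked which transcripts differed after 72 h with cadmium, and the study's title names SNAI1, a transcription factor that represses E-cadherin, and the microRNA miR-30e. Metallothioneins, small cysteine-rich proteins that bind cadmium and zinc, had the largest list median among the 30 lists tested, and SNAI1 rose from a low level. Genes of hypoxia and glycolysis, of cholesterol synthesis and of epithelial junctions were on balance higher, and genes of mitosis, the proteasome, the ATF4 response and the interferon response were on balance lower. These lists passed camera with a preset correlation, but had an adjusted p = 0.344 or more with an estimated correlation. Nuclear-retained RNAs, which also serve as signs of RNA quality, were on balance higher too (median log2 fold change 0.59). Without control replicate 1 the junction median moved from 0.75 to 0.43 and the interferon median from -0.94 to -0.36. The cholesterol median then moved from 0.20 to 0.31 and the ATF4 median from -0.48 to -0.60. Of 1209 higher and 1046 lower genes among 13663 tested (edgeR, Benjamini-Hochberg adjusted p under 0.05), 466 of the higher and 54 of the lower differed by more than 2-fold. With each library scaled by its total alone, 1445 were higher and 682 lower, a share of 67.9% higher against 53.6%. Leaving out 1 library gave 1977 higher and 1791 lower without control replicate 2, 369 and 235 without cadmium replicate 1, and 594 and 295 without cadmium replicate 2. Counts simulated with each gene's own dispersion and 200 changed genes per draw gave 14.2% false calls at this threshold. That share depends on how many genes change and by how much, so it is not the false share of the calls above.

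SNAI1 (chromosome 20, 48599513 to 48605420 in hg19) had 51 and 8 reads in the controls and 239 and 73 in the cadmium libraries. It rose from 1.45 ± 0.713 to 6.21 ± 2.25 CPM (SD, n = 2 each), a log2 fold change of 1.96 (SE 0.37, adjusted p = 0.0141, edgeR). The authors' deposited table lists SNAI1 at a mean of 0.743 RPKM in control and 3.24 RPKM in cadmium, with a log2 ratio of 0.99 and an adjusted p of 0.000794. Of 8 tested transcription factors of the epithelial-mesenchymal transition (EMT), SNAI1, ZEB1 and SNAI3 rose, 0 fell and 5 did not pass, and 3 rose and 0 fell when adjusted over the list alone. ZEB1, which also represses epithelial genes, rose by 1.94 on the log2 scale (SE 0.32, adjusted p = 0.00980), from 1.41 ± 0.526 to 4.91 ± 0.679 CPM, and SNAI3 rose by 1.14 (SE 0.33, adjusted p = 0.0463). Over all tested members the median log2 fold change was 0.20, and the list did not pass camera (adjusted p = 0.0759). Random lists matched on expression had a median of 0.13, and the EMT list median exceeded those of 63.3% of them. The EMT list median was 0.48 without control replicate 1. Higher EMT factors numbered 1 without cadmium replicate 1. Lower EMT factors numbered 1 without control replicate 2. SNAI3 without control replicate 1 (adjusted p = 0.162), SNAI1 and SNAI3 without cadmium replicate 1 (adjusted p from 0.0683 to 0.264), and SNAI3 without cadmium replicate 2 (adjusted p = 0.211) no longer passed. SNAI3 with DESeq2, level-dependent scaling and counts thinned to equal depth (adjusted p from 0.121 to 0.293) also missed the threshold. SNAI3 moved to 0.70 with counts thinned to equal depth.

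**Figure D1:**
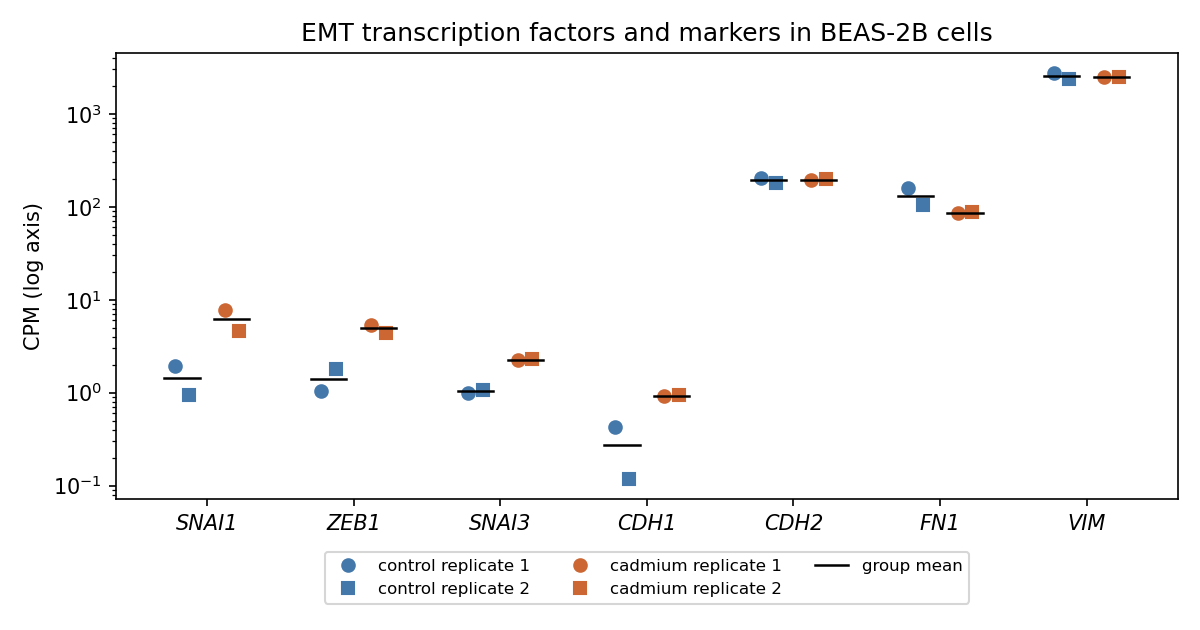
Level of EMT transcription factors and markers in CPM (log axis) in 2 control libraries (blue) and 2 cadmium libraries (orange), with bars at group means. SNAI1 lies at 1.96 and 0.950 CPM in the controls and at 7.81 and 4.62 CPM in the cadmium libraries.

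Among EMT markers, none of CDH1, VIM, CDH2 and FN1 passed the test. CDH1, which encodes E-cadherin, had 11 and 1 reads in the controls and 28 and 15 with cadmium, and a log2 fold change of 1.45 (SE 0.53, adjusted p = 0.0944). The value for CDH1 was 2.90 without control replicate 1 and 0.93 with level-dependent scaling. VIM, encoding vimentin, stood at 2551 ± 247 CPM in control and 2496 ± 13.5 CPM with cadmium (log2 fold change -0.032, SE 0.084, adjusted p = 0.830). CDH2, encoding N-cadherin, had a log2 fold change of 0.018 (SE 0.088, adjusted p = 0.908). VIM turned to 0.070 without control replicate 1, 0.027 with library size alone, 0.0064 with the stricter filter and 0.064 with level-dependent scaling. CDH2 turned to -0.074 without control replicate 2. FN1, encoding fibronectin, had a log2 fold change of -0.62 (SE 0.20, adjusted p = 0.0858). It passed with DESeq2 (adjusted p = 0.00453) and with edgeR without control replicate 2 (adjusted p = 9.28e-06). The value for FN1 was -0.26 without control replicate 1. The authors' deposited table gives FN1 a log2 ratio of -0.54 and an adjusted p of 0.00675. Of 20 mesenchymal and matrix genes, the integrin gene ITGA5 rose by 0.34 and 18 did not pass. The matrix gene POSTN fell by 2.21 on the log2 scale (SE 0.42, adjusted p = 0.0132). The authors' deposited table lists POSTN at a low level, 0.559 RPKM in control and 0.141 RPKM in cadmium, with a log2 ratio of -0.64. Adjusted over the list alone, 1 of the 20 genes rose and 1 fell. As a list these genes had a median log2 fold change of -0.13, and the list did not pass camera (adjusted p = 0.0868). The median was -0.10 (camera adjusted p = 0.00100) without control replicate 2, -0.19 (camera adjusted p = 0.0448) without cadmium replicate 1, -0.078 without cadmium replicate 2, -0.068 with library size alone and -0.030 with the stricter filter. Higher mesenchymal genes numbered 0 without either cadmium replicate. Lower mesenchymal genes numbered 7 without control replicate 2, 0 without cadmium replicate 1, 5 with DESeq2 and 2 with limma-voom. POSTN without control replicate 1 (adjusted p = 0.0801), ITGA5 and POSTN without cadmium replicate 1 (adjusted p from 0.0622 to 0.226), and ITGA5 and POSTN without cadmium replicate 2 (adjusted p from 0.0501 to 0.0562) no longer passed.

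Epithelial junction genes and keratins were on balance higher. Of 22 tested, 7 rose, 3 fell and 12 did not pass, and 8 rose and 3 fell when adjusted over the list alone. The tight junction scaffold gene TJP3 rose by 2.56 on the log2 scale (SE 0.28, adjusted p = 0.00313), the desmosome gene DSP by 1.64 and EPCAM by 1.36. The list median was 0.75 on the log2 scale and camera gave an adjusted p of 0.00379, or adjusted p = 0.518 with an estimated correlation. The median was 0.43 (camera adjusted p = 0.136) without control replicate 1. Higher junction genes and keratins numbered 11 without control replicate 2 and 4 without cadmium replicate 1. Of 6 basal airway cell genes 3 rose and 0 fell, among them KRT15 by 2.56 and NGFR by 1.60. The authors' deposited table lists KRT15 at a low level, a mean of 0.0645 RPKM in control and 0.414 RPKM in cadmium. DESeq2 gave no adjusted p for 1 of the 3 basal cell genes that rose. Adjusted over the list alone, 4 rose and 0 fell. Over all tested members the median log2 fold change was 1.37 and camera gave an adjusted p of 0.00243, or adjusted p = 0.518 with an estimated correlation. The median was 0.91 (camera adjusted p = 0.00933) without cadmium replicate 1. Higher basal cell genes numbered 0 without cadmium replicate 1 and 1 without cadmium replicate 2. KRT15 without control replicate 1 (adjusted p = 0.106), DSP, EPCAM, KRT15 and NGFR without cadmium replicate 1 (adjusted p from 0.0596 to 0.237), and KRT15 without cadmium replicate 2 (adjusted p = 0.0540) no longer passed. KRT15 with level-dependent scaling (adjusted p = 0.0614) also missed the threshold. DSP moved to 2.50 without control replicate 1.

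Few markers of other cell types were tested, and such lists were too short for camera. Of 12 leukocyte genes 3 were tested, and CD68, a lysosomal protein that other cells also make, rose by 0.59 (adjusted p = 0.00857). Of 8 endothelial genes 2 were tested, and TIE1 rose by 1.68, from 0.875 ± 0.229 to 2.98 ± 0.453 CPM. Adjusted over the list alone, 1 leukocyte and 1 endothelial gene rose. TPPP3, the 1 tested gene of differentiated airway cells, had a log2 fold change of 1.10 that did not pass (adjusted p = 0.160). The value for TPPP3 was 0.69 without control replicate 1, 0.48 without cadmium replicate 1 and 0.66 with level-dependent scaling. Among 4 tested fibroblast genes 0 passed with edgeR, also when adjusted over the list alone, 1 had an unadjusted p under 0.05, and 1 passed with DESeq2 and 0 with limma-voom. The collagen gene COL1A1 had a log2 fold change of -0.32 (adjusted p = 0.0690). COL1A1 passed with DESeq2 (adjusted p = 0.0384) and with edgeR with no filter (adjusted p = 0.0294) and without control replicate 2 (adjusted p = 0.000618). The value for COL1A1 was -0.16 without control replicate 1. TIE1 without cadmium replicate 1 (adjusted p = 0.126) no longer passed. TIE1 with counts thinned to equal depth (adjusted p = 0.0929) also missed the threshold.

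All 8 tested metallothionein genes rose, and 8 rose and 0 fell when adjusted over the list alone. MT2A rose from 328 ± 71.2 to 3456 ± 199 CPM (log2 fold change 3.40, SE 0.16, adjusted p = 0.000567). MT1E rose by 5.02 (SE 0.16), MT1F by 5.26 (SE 0.23) and MT1X by 5.47 (SE 0.40) on the log2 scale. MT1B and MT1G had 0 reads in both controls and were at least 111-fold and at least 12.9-fold higher with cadmium, taken against 3 reads over the control group. MT1A had 2 reads in the controls and 56 with cadmium, a ratio of 20.8 with a 95% counting interval from 5.49 to 176. These genes are near-identical copies, so the split of reads among them is uncertain. As a list these genes had a median log2 fold change of 5.14 and camera gave an adjusted p of 5.90e-54, or adjusted p = 0.344 with an estimated correlation. Higher metallothionein genes numbered 5 without control replicate 1 and 5 with DESeq2, which gave no adjusted p for 3 of those that rose. With genes at 0 placed at their bound the median was 4.67. MT1X without control replicate 1 (adjusted p = 0.184), and MT1X without control replicate 2 (adjusted p = 0.167) no longer passed.

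**Figure D2:**
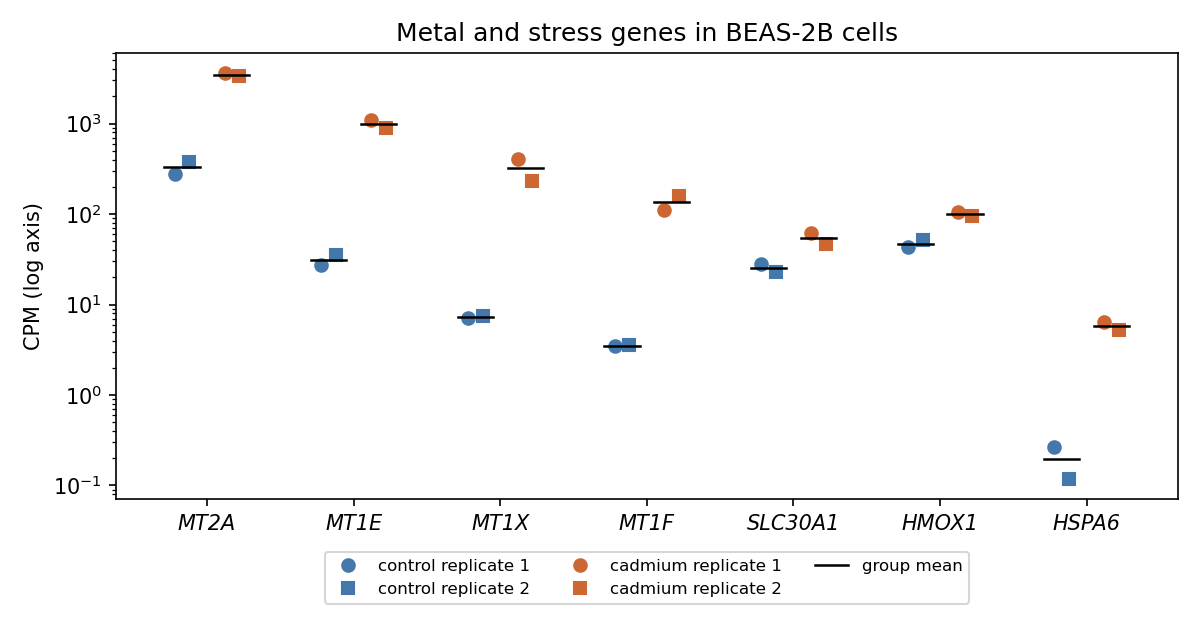
Level of metal and stress genes in CPM (log axis) in 2 control libraries (blue) and 2 cadmium libraries (orange), with bars at group means. For each of the 7 genes both cadmium libraries lie above both controls, and MT2A lies at 277 and 378 CPM in the controls and at 3596 and 3315 CPM with cadmium.

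Of 20 zinc and divalent metal transporter genes 5 rose, 0 fell and 15 did not pass, and 5 rose and 0 fell when adjusted over the list alone. SLC30A1, which exports zinc from the cell, rose by 1.08 (SE 0.16, adjusted p = 0.00713), from 25.5 ± 3.31 to 54.5 ± 10.7 CPM. SLC30A2 had 0 reads in the controls and was at least 36.9-fold higher, and the importer gene SLC39A8 rose by 1.34 (adjusted p = 0.0429). The list median was 0.11 on the log2 scale and camera gave an adjusted p of 0.0322, or adjusted p = 0.518 with an estimated correlation. The median exceeded those of 93.5% of random lists matched on expression, whose median was -0.014. The median was 0.14 (camera adjusted p = 0.0762) without control replicate 2, 0.057 (camera adjusted p = 0.00933) without cadmium replicate 1, 0.17 (camera adjusted p = 0.0275) with library size alone and 0.13 (camera adjusted p = 0.0644) with the stricter filter. Higher metal transporter genes numbered 3 without control replicate 1 and 3 with level-dependent scaling. Of 8 iron-handling genes 3 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone. The ferritin light chain gene FTL rose by 0.78 (SE 0.074, adjusted p = 0.00234), and the transferrin receptor gene TFRC fell by 0.67 on the log2 scale (adjusted p = 0.0410). Over all tested members the median log2 fold change was 0.11, and the list did not pass camera (adjusted p = 0.160). The median was 0.23 without cadmium replicate 1, 0.17 with library size alone, 0.18 with the stricter filter and 0.17 (camera adjusted p = 0.0488) with level-dependent scaling. Higher iron-handling genes numbered 1 without cadmium replicate 1. Lower iron-handling genes numbered 0 without control replicate 1, 0 without cadmium replicate 1 and 0 with level-dependent scaling. SLC30A2, SLC39A8 and TFRC without control replicate 1 (adjusted p from 0.0547 to 0.156), and SLC39A8 and TFRC without cadmium replicate 1 (adjusted p from 0.127 to 0.401) no longer passed. SLC39A8 with DESeq2, level-dependent scaling and counts thinned to equal depth (adjusted p from 0.0852 to 0.132), and TFRC with library size alone, no filter, the stricter filter and level-dependent scaling (adjusted p from 0.0501 to 0.104) also missed the threshold. SLC39A8 moved to 0.88 without cadmium replicate 1.

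Of 22 NRF2 antioxidant genes 3 rose, 0 fell and 19 did not pass, and 3 rose and 0 fell when adjusted over the list alone. HMOX1, which degrades heme, rose by 1.12 (SE 0.12, adjusted p = 0.00285), from 46.9 ± 5.91 to 101 ± 7.55 CPM, and AKR1C3 rose by 1.66. As a list these genes had a median log2 fold change of 0.15, and the list did not pass camera (adjusted p = 0.0663). The median was 0.18 (camera adjusted p = 0.0393) without cadmium replicate 1, 0.073 without cadmium replicate 2, 0.21 (camera adjusted p = 0.0469) with library size alone, 0.15 (camera adjusted p = 0.0438) with no filter, 0.23 (camera adjusted p = 0.0108) with level-dependent scaling and 0.078 with counts thinned to equal depth. Higher NRF2 genes numbered 1 without cadmium replicate 1. Lower NRF2 genes numbered 1 without control replicate 1. Of 22 heat shock genes 4 rose and 0 fell, and 4 rose and 0 fell when adjusted over the list alone. HSPA6, an inducible chaperone gene, rose by 4.63 (SE 0.40, adjusted p = 0.00181), from 0.194 ± 0.106 to 5.78 ± 0.835 CPM. This control mean lies below 0.356 CPM, the level of 3 reads in control replicate 2, so the size of the rise is uncertain. HSPA1B and HSPA1A, near-identical copies whose reads may be split between them, rose by 0.82 and 0.71. Heat shock genes had a median log2 fold change of 0.074 and did not pass camera (adjusted p = 0.0680). The median was 0.38 (camera adjusted p = 1.01e-06) without control replicate 1, -0.14 (camera adjusted p = 0.592) without control replicate 2, 0.18 (camera adjusted p = 0.00191) without cadmium replicate 1, -0.038 without cadmium replicate 2, 0.13 with library size alone, 0.11 with the stricter filter and 0.13 (camera adjusted p = 0.0108) with level-dependent scaling. Higher heat shock genes numbered 9 without control replicate 1 and 2 without cadmium replicate 2. Lower heat shock genes numbered 4 without control replicate 2. Of 19 endoplasmic reticulum chaperone genes HSP90B1 and MANF rose, by 0.53 and 0.34, 0 fell, and 1 rose and 0 fell when adjusted over the list alone. Chaperone genes had a median log2 fold change of 0.027 and did not pass camera (adjusted p = 0.605). The median was 0.055 without control replicate 1, -0.011 (camera adjusted p = 0.735) without control replicate 2, 0.057 without cadmium replicate 1, 0.0025 (camera adjusted p = 0.958) without cadmium replicate 2, 0.085 with library size alone, 0.065 with the stricter filter, 0.12 with level-dependent scaling and 0.054 with counts thinned to equal depth. Higher chaperone genes numbered 1 without control replicate 2, 1 without cadmium replicate 2 and 1 with DESeq2. Lower chaperone genes numbered 2 without control replicate 2. MANF without control replicate 2 (adjusted p = 0.0732), AKR1C3 and MANF without cadmium replicate 1 (adjusted p from 0.0994 to 0.204), and HSPA1A and MANF without cadmium replicate 2 (adjusted p from 0.0586 to 0.326) no longer passed. AKR1C3 with DESeq2 (adjusted p = 0.0664), and MANF with DESeq2 (adjusted p = 0.0559) also missed the threshold.

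Of 21 ATF4 targets 4 fell, 0 rose and 17 did not pass, and 1 rose and 4 fell when adjusted over the list alone. The amino acid transporter gene SLC7A5 fell from 784 ± 136 to 337 ± 16.4 CPM (log2 fold change -1.21, SE 0.12, adjusted p = 0.00263), and its partner SLC3A2 fell by 0.82. As a list these genes had a median log2 fold change of -0.48 and camera gave an adjusted p of 0.000351, or adjusted p = 0.551 with an estimated correlation. The median was -0.29 (camera adjusted p = 0.0173) without cadmium replicate 2. Higher ATF4 targets numbered 2 without either control replicate, 1 with level-dependent scaling, 1 with DESeq2 and 1 with limma-voom. Lower ATF4 targets numbered 7 without control replicate 1, 10 without cadmium replicate 1, 2 without cadmium replicate 2 and 6 with DESeq2. Of 31 proteasome subunit genes 11 fell, 0 rose and 20 did not pass, and 0 rose and 17 fell when adjusted over the list alone. PSMB6 fell by 0.42 (SE 0.086, adjusted p = 0.0169) and PSMA7 fell by 0.40. Proteasome genes had a median log2 fold change of -0.26 and passed camera (adjusted p = 3.77e-06), but had an adjusted p = 0.545 with an estimated correlation. Lower proteasome genes numbered 0 without cadmium replicate 1, 1 without cadmium replicate 2 and 3 with level-dependent scaling. PSMB6 and PSMA7 without cadmium replicate 1 (adjusted p from 0.0996 to 0.127), and PSMA7 without cadmium replicate 2 (adjusted p = 0.0531) no longer passed.

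Of 17 hypoxia and glycolysis genes 10 rose, 0 fell and 7 did not pass, and 12 rose and 1 fell when adjusted over the list alone. EGLN3, a prolyl hydroxylase that acts on HIF, rose by 1.93 (SE 0.35, adjusted p = 0.0117), PFKFB4 by 1.27, BNIP3 by 1.12 and HK2, a hexokinase, by 0.96. Over all tested members the median log2 fold change was 0.68 and camera gave an adjusted p of 1.93e-08, or adjusted p = 0.518 with an estimated correlation. Higher hypoxia genes numbered 5 without cadmium replicate 1. Lower hypoxia genes numbered 1 without control replicate 2. Of 23 genes of cholesterol synthesis and uptake 9 rose and 0 fell, and 9 rose and 0 fell when adjusted over the list alone. INSIG1, a regulator of sterol synthesis, rose by 1.46 (SE 0.14, adjusted p = 0.00241) and MSMO1 by 0.87. Cholesterol genes had a median log2 fold change of 0.20 and passed camera (adjusted p = 0.000228), but had an adjusted p = 0.518 with an estimated correlation. The median was 0.31 (camera adjusted p = 1.85e-06) without control replicate 1. Higher cholesterol genes numbered 5 without cadmium replicate 1 and 4 without cadmium replicate 2. Of 16 autophagy and lysosome genes 4 rose and 0 fell, among them GABARAPL1 by 0.52 (adjusted p = 0.0101), and 8 rose and 0 fell when adjusted over the list alone. Autophagy genes had a median log2 fold change of 0.25 and passed camera (adjusted p = 0.0286), but had an adjusted p = 0.518 with an estimated correlation. The median was 0.18 (camera adjusted p = 0.101) without control replicate 2 and 0.28 (camera adjusted p = 0.0548) without cadmium replicate 2. Higher autophagy genes numbered 1 without either cadmium replicate and 7 with level-dependent scaling. EGLN3 without cadmium replicate 1 (adjusted p = 0.0805) no longer passed.

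**Figure D3:**
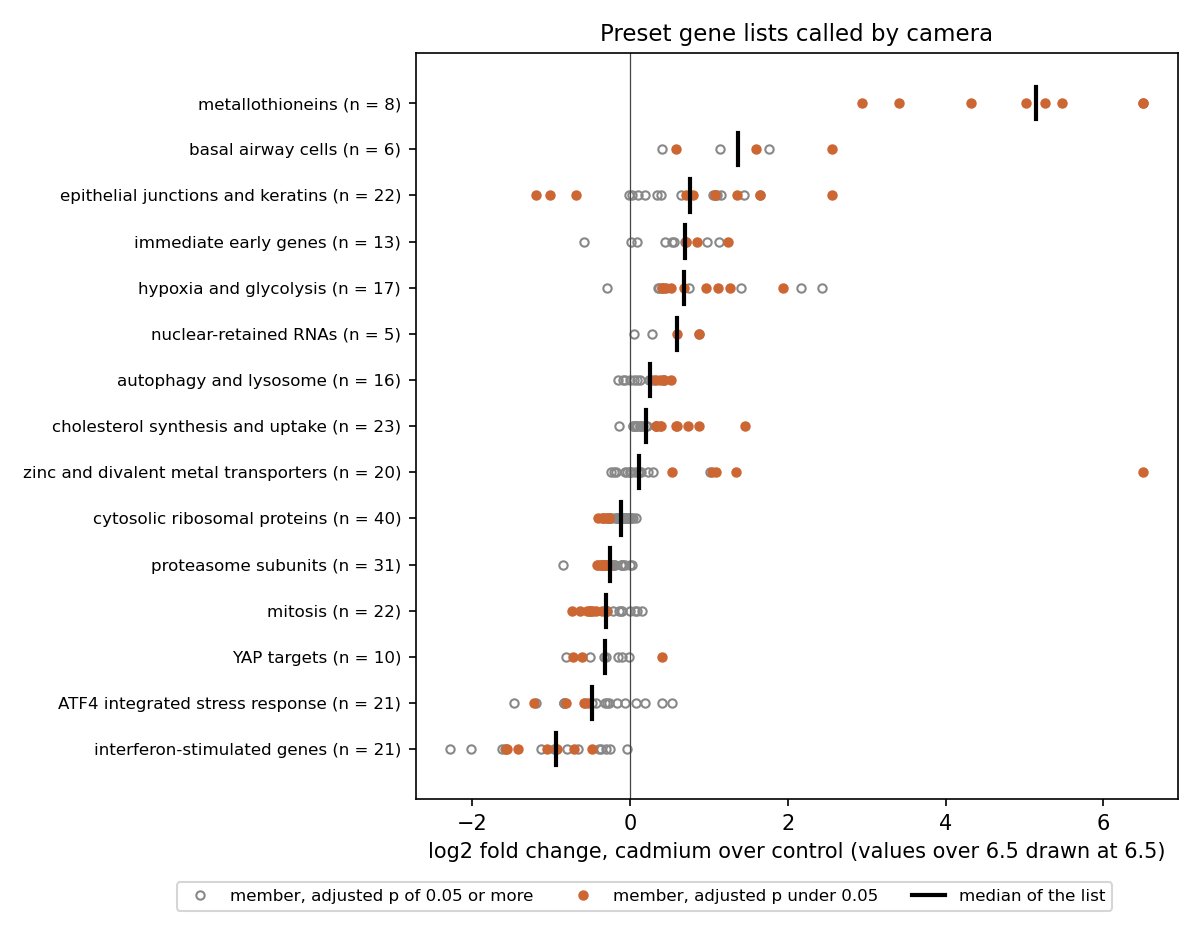
Log2 fold change, cadmium over control, of the tested members of the 15 preset gene lists that passed camera with a preset correlation; filled circles are members with an edgeR adjusted p under 0.05, open circles the others, bars list medians, and values over 6.5 are drawn at 6.5. All 8 metallothioneins are filled and lie right of 0, and the interferon list has the lowest median of the 15 at -0.94.

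Of 22 mitosis genes 12 fell, 0 rose and 10 did not pass, and 0 rose and 14 fell when adjusted over the list alone. The mitotic kinase gene PLK1 fell by 0.73 on the log2 scale (SE 0.077, adjusted p = 0.00307), from 474 ± 14.7 to 285 ± 7.21 CPM, and AURKA fell by 0.64. Over all tested members the median log2 fold change was -0.31 and camera gave an adjusted p of 1.50e-06, or adjusted p = 0.518 with an estimated correlation. Lower mitosis genes numbered 5 without cadmium replicate 1 and 6 without cadmium replicate 2. Of 27 DNA replication genes CDT1 and RFC4 rose, by 0.51 and 0.42, TYMS fell by 0.34, and 2 rose and 0 fell when adjusted over the list alone. Replication genes had a median log2 fold change of -0.069 and did not pass camera (adjusted p = 0.355). The median was -0.13 without control replicate 1, -0.042 without control replicate 2, -0.011 with library size alone, -0.031 with the stricter filter and 0.0043 (camera adjusted p = 0.763) with level-dependent scaling. Higher replication genes numbered 1 without control replicate 1, 1 without cadmium replicate 2 and 0 without cadmium replicate 1. Lower replication genes numbered 0 without either cadmium replicate and 0 with level-dependent scaling. Of 20 DNA repair genes 3 rose and 2 fell, and 3 rose and 2 fell when adjusted over the list alone. XRCC2 rose by 0.62 and XPA fell by 0.71. Repair genes had a median log2 fold change of 0.085 and did not pass camera (adjusted p = 0.577). The median was 0.023 without control replicate 2 and 0.14 with library size alone. Higher repair genes numbered 1 without control replicate 1, 5 without control replicate 2 and 0 without either cadmium replicate. Lower repair genes numbered 0 without either cadmium replicate, 1 with level-dependent scaling and 1 with DESeq2. CDT1, TYMS and XRCC2 without control replicate 1 (adjusted p from 0.0507 to 0.141), CDT1, RFC4, TYMS, XRCC2 and XPA without cadmium replicate 1 (adjusted p from 0.0666 to 0.201), and RFC4, TYMS, XRCC2 and XPA without cadmium replicate 2 (adjusted p from 0.0750 to 0.242) no longer passed. TYMS with DESeq2 size factors, library size alone, the stricter filter, level-dependent scaling, counts thinned to equal depth and without read-through models (adjusted p from 0.0506 to 0.154), and XPA with DESeq2 (adjusted p = 0.0773) also missed the threshold. CDT1 moved to 0.32 without cadmium replicate 1 and TYMS moved to -0.21 without control replicate 1.

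Of 21 p53 targets 1 rose, 5 fell and 15 did not pass, and 2 rose and 6 fell when adjusted over the list alone. TP53I3 fell by 0.85 (SE 0.15, adjusted p = 0.0103), MDM2, which encodes the ligase that degrades p53, fell by 0.51, and PMAIP1 rose by 0.48. Over all tested members the median log2 fold change was -0.24, and the list did not pass camera (adjusted p = 0.0759). The median was -0.021 (camera adjusted p = 0.914) without control replicate 1, -0.34 (camera adjusted p = 0.000494) without control replicate 2, -0.32 (camera adjusted p = 0.0113) without cadmium replicate 1, -0.12 without cadmium replicate 2, -0.24 (camera adjusted p = 0.0472) with no filter and -0.16 with level-dependent scaling. Higher p53 targets numbered 3 without control replicate 1, 0 without either cadmium replicate and 2 with limma-voom. Lower p53 targets numbered 2 without control replicate 1, 10 without control replicate 2, 1 without either cadmium replicate and 3 with level-dependent scaling. Of 17 apoptosis regulators 2 rose and 2 fell, and 2 rose and 2 fell when adjusted over the list alone. The proapoptotic gene BCL2L11 rose by 1.08 (SE 0.17, adjusted p = 0.00853), while BCL2L1 fell by 0.45 and BAX fell by 0.36. Apoptosis genes had a median log2 fold change of -0.085 and did not pass camera (adjusted p = 0.819). The median was 0.15 (camera adjusted p = 0.294) without control replicate 1, -0.20 without control replicate 2, -0.078 (camera adjusted p = 0.958) without cadmium replicate 2, -0.027 with library size alone and -0.042 (camera adjusted p = 0.970) with level-dependent scaling. Higher apoptosis genes numbered 1 without either cadmium replicate and 1 without control replicate 2. Lower apoptosis genes numbered 1 without control replicate 1, 1 with level-dependent scaling, 5 without control replicate 2 and 0 without either cadmium replicate. The list mean was 0.054, opposite in sign to the median. BAX without control replicate 1 (adjusted p = 0.0558), PMAIP1 without control replicate 2 (adjusted p = 0.0607), MDM2, PMAIP1, BCL2L1 and BAX without cadmium replicate 1 (adjusted p from 0.0581 to 0.215), and MDM2, PMAIP1, BCL2L1 and BAX without cadmium replicate 2 (adjusted p from 0.0632 to 0.222) no longer passed. PMAIP1 with counts thinned to equal depth (adjusted p = 0.0506), and BAX with library size alone and level-dependent scaling (adjusted p from 0.0540 to 0.0952) also missed the threshold. PMAIP1 moved to 0.31 without control replicate 2.

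Of 21 interferon-stimulated genes 7 fell, 0 rose and 14 did not pass, and 0 rose and 8 fell when adjusted over the list alone. The antiviral gene MX1 stood at 61.7 and 33.9 CPM in control replicates 1 and 2 and at 17.6 and 15.3 CPM with cadmium (log2 fold change -1.56, SE 0.30, adjusted p = 0.0280). OASL fell by 1.58 and IFIT3 fell by 1.06. The list median was -0.94 on the log2 scale and camera gave an adjusted p of 1.50e-06, or adjusted p = 0.551 with an estimated correlation. The median was -0.36 (camera adjusted p = 0.000314) without control replicate 1. Lower interferon-stimulated genes numbered 19 without control replicate 2, 1 without cadmium replicate 1 and 2 without cadmium replicate 2. Of 17 cytokine and NF-kB genes NFKB2 rose by 0.50, the cytokine gene IL1B fell by 0.89, and 1 rose and 2 fell when adjusted over the list alone. Cytokine genes had a median log2 fold change of -0.10 and did not pass camera (adjusted p = 0.409). The median was 0.036 (camera adjusted p = 0.403) without control replicate 1, -0.089 (camera adjusted p = 0.0251) without control replicate 2, -0.27 without cadmium replicate 1, 0.055 without cadmium replicate 2, -0.044 with library size alone and -0.064 with the stricter filter. Higher cytokine genes numbered 3 without control replicate 1 and 0 without cadmium replicate 1. Lower cytokine genes numbered 6 without control replicate 2, 0 without cadmium replicate 2, 2 with level-dependent scaling and 2 with limma-voom. Of 13 immediate early genes 3 rose and 0 fell, FOSB by 1.24, NR4A1 by 0.85 and ZFP36 by 0.71, and 3 rose and 0 fell when adjusted over the list alone. Immediate early genes had a median log2 fold change of 0.70 and passed camera (adjusted p = 0.0157), but had an adjusted p = 0.707 with an estimated correlation. The median was 1.11 (camera adjusted p = 5.77e-26) without control replicate 1, 0.33 (camera adjusted p = 0.735) without control replicate 2 and 0.53 (camera adjusted p = 0.0794) without cadmium replicate 1. Higher immediate early genes numbered 12 without control replicate 1, 1 without cadmium replicate 1 and 1 with level-dependent scaling. Lower immediate early genes numbered 2 without control replicate 2. MX1, IFIT3, NFKB2, FOSB and ZFP36 without cadmium replicate 1 (adjusted p from 0.0737 to 0.287), and MX1, IFIT3, IL1B and ZFP36 without cadmium replicate 2 (adjusted p from 0.0508 to 0.316) no longer passed. MX1 with no filter (adjusted p = 0.153), FOSB with level-dependent scaling (adjusted p = 0.0762), and ZFP36 with level-dependent scaling (adjusted p = 0.0554) also missed the threshold. MX1 moved to -1.03 without control replicate 1, IFIT3 moved to -0.64 without control replicate 1, FOSB moved to 2.05 without control replicate 1, ZFP36 moved to 1.11 without control replicate 1 and ZFP36 moved to 0.45 without control replicate 2.

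Of 16 TGF-beta pathway genes 4 fell, 0 rose and 12 did not pass, and 0 rose and 4 fell when adjusted over the list alone. The inhibitor gene SMAD7 fell by 0.90 (SE 0.17, adjusted p = 0.0134) and the ligand gene TGFB2 fell by 0.70. The list median was -0.061 on the log2 scale, and the list did not pass camera (adjusted p = 0.176). The median was 0.11 (camera adjusted p = 0.771) without control replicate 1, -0.12 (camera adjusted p = 0.000327) without control replicate 2, -0.14 without cadmium replicate 2, -0.0033 with library size alone and -0.030 with counts thinned to equal depth. Higher TGF-beta genes numbered 3 without control replicate 1, 1 without cadmium replicate 2 and 1 with DESeq2. Lower TGF-beta genes numbered 1 without cadmium replicate 1. Of 10 YAP targets AJUBA fell by 0.73 and AMOTL2 fell by 0.62, while AMOTL1 rose by 0.41, and 1 rose and 3 fell when adjusted over the list alone. YAP targets had a median log2 fold change of -0.31 and passed camera (adjusted p = 0.0409), but had an adjusted p = 0.551 with an estimated correlation. The median was -0.12 (camera adjusted p = 0.463) without control replicate 1, -0.61 (camera adjusted p = 3.67e-06) without control replicate 2, -0.46 (camera adjusted p = 0.0989) without cadmium replicate 1, -0.28 (camera adjusted p = 0.0644) with the stricter filter and -0.26 (camera adjusted p = 0.120) with level-dependent scaling. Higher YAP targets numbered 2 without control replicate 1 and 0 without either cadmium replicate. Lower YAP targets numbered 6 without control replicate 2. Of 12 matrix protease and inhibitor genes MMP3, a stromelysin, rose by 2.93 (SE 0.28, adjusted p = 0.00234) and PLAUR by 0.50, and 2 rose and 0 fell when adjusted over the list alone. Protease genes had a median log2 fold change of 0.11 and did not pass camera (adjusted p = 0.0910). The median was 0.27 (camera adjusted p = 0.00468) without control replicate 1, 0.025 (camera adjusted p = 0.735) without control replicate 2, 0.17 with library size alone and 0.15 (camera adjusted p = 0.0445) with level-dependent scaling. Higher protease genes numbered 1 without cadmium replicate 1. Lower protease genes numbered 1 without control replicate 1 and 2 without control replicate 2. SMAD7, TGFB2, AMOTL1 and PLAUR without cadmium replicate 1 (adjusted p from 0.0644 to 0.127), and AMOTL1 without cadmium replicate 2 (adjusted p = 0.172) no longer passed. TGFB2 with counts thinned to equal depth (adjusted p = 0.0560) also missed the threshold.

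Of 40 cytosolic ribosomal protein genes 6 fell, 0 rose and 34 did not pass, among them RPS15, which fell by 0.40, and 0 rose and 6 fell when adjusted over the list alone. The list median was -0.12 on the log2 scale and camera gave an adjusted p of 0.00406, or adjusted p = 0.707 with an estimated correlation. The median exceeded those of 43.1% of random lists matched on expression, whose median was -0.11. The median was -0.090 (camera adjusted p = 0.0707) without control replicate 2, -0.057 (camera adjusted p = 0.0114) with library size alone and -0.017 (camera adjusted p = 0.278) with level-dependent scaling. Lower ribosomal genes numbered 0 without either cadmium replicate and 1 with level-dependent scaling. The nuclear-retained RNAs MALAT1 and NEAT1, which also serve as signs of RNA quality, rose by 0.87 and 0.59 of 5 tested, and 3 rose and 0 fell when adjusted over the list alone. Nuclear-retained RNAs had a median log2 fold change of 0.59 and passed camera (adjusted p = 0.00409), but had an adjusted p = 0.518 with an estimated correlation. The median was 0.35 (camera adjusted p = 0.00971) without control replicate 1. Higher nuclear-retained RNAs numbered 1 without either cadmium replicate. Of 7 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, HIST1H2AC fell by 1.37, and 0 rose and 2 fell when adjusted over the list alone. Histone genes had a median log2 fold change of -0.67 and did not pass camera (adjusted p = 0.0534). The median was -0.43 without control replicate 1, -0.57 (camera adjusted p = 0.0308) without cadmium replicate 1, -0.61 (camera adjusted p = 0.0306) with library size alone and -0.80 (camera adjusted p = 0.00511) with level-dependent scaling. Lower histone genes numbered 2 without either control replicate, 2 with level-dependent scaling and 2 with limma-voom. RPS15 and NEAT1 without cadmium replicate 1 (adjusted p from 0.0570 to 0.106), and RPS15 and NEAT1 without cadmium replicate 2 (adjusted p from 0.0518 to 0.0581) no longer passed.

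The mature miR-30e is not measured by these libraries. Its precursor gene MIR30E (chromosome 1, 41220027 to 41220118 in hg19) had 0 reads in all 4 libraries. The host gene NFYC had a log2 fold change of -0.30 (SE 0.10, adjusted p = 0.0744) that did not pass, except without control replicate 2 (edgeR adjusted p = 0.0226). Of 17 reported miR-30 family targets 1 rose, 2 fell and 14 did not pass, and 1 rose and 2 fell when adjusted over the list alone. SNAI1 rose, and the neurotrophin gene BDNF fell by 0.86 (SE 0.13, adjusted p = 0.00820). The list median was -0.042 on the log2 scale, and the list did not pass camera (adjusted p = 0.952). The median was 0.18 without control replicate 1, -0.13 (camera adjusted p = 0.162) without control replicate 2, -0.077 without cadmium replicate 1, 0.016 (camera adjusted p = 0.996) with library size alone, -0.042 (camera adjusted p = 0.976) with no filter, -0.048 (camera adjusted p = 0.554) with the stricter filter and 0.0015 with counts thinned to equal depth. Higher miR-30 targets numbered 2 without control replicate 1, 2 with limma-voom, 3 without control replicate 2 and 0 without cadmium replicate 1. Lower miR-30 targets numbered 4 without control replicate 2, 1 without either cadmium replicate, 1 with level-dependent scaling and 1 with DESeq2. The list mean was 0.11, opposite in sign to the median. The 3' UTR of SNAI1, 830 bases long, holds 1 copy of the miR-30 8-mer site TGTTTACA. The 1114 tested genes with this site had a median log2 fold change of 0.073, against -0.014 for 9587 genes with a 3' UTR and no site. The difference of 0.087 lay above 97.8% of those for 827 control words of the same bases, whose median was 0.046 (2-sided permutation p = 0.0459). It missed the threshold with 1 library left out (permutation p = 0.413 and 0.0531 without control replicates 1 and 2, and 0.0918 without either cadmium replicate). As a set these genes did not pass camera (adjusted p = 0.0639, and adjusted p = 0.462 with an estimated correlation). Genes are not independent replicates.

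Outside the lists, and among named genes with reads in the controls, DENND2A had the largest rise (2.51 on the log2 scale, SE 0.19, adjusted p = 0.00158). PPFIA4 rose by 2.50, the protease gene TMPRSS3 by 2.36 and the repressor gene HES7 by 2.34. The read-through models ATP5J2-PTCD1 and C7orf55-LUC7L2, which join neighbouring genes, had 0 reads in both controls, 619 and 286, and 258 and 217, in the cadmium libraries, and were at least 224-fold and at least 118-fold higher. Reads of such models can be assigned to the overlapping genes instead. Summed with ATP5J2, ATP5J2-PTCD1 stood at 152 ± 2.89 CPM in control and 148 ± 1.79 CPM with cadmium (log2 ratio -0.038), and summed with PTCD1 at 71.5 ± 7.40 CPM in control and 56.7 ± 6.87 CPM with cadmium (log2 ratio -0.33). Summed with C7orf55, C7orf55-LUC7L2 stood at 26.7 ± 0.0747 CPM in control and 25.1 ± 1.16 CPM with cadmium (log2 ratio -0.086), and summed with LUC7L2 at 124 ± 6.43 CPM in control and 102 ± 5.87 CPM with cadmium (log2 ratio -0.28). With library size alone the log2 ratio of the sum with ATP5J2 turned to 0.020 and that with C7orf55 was -0.028. These sums were not tested. VIM-AS1 fell by 1.79 (SE 0.21, adjusted p = 0.00349). Whether strand was used in counting is not given, and without it VIM-AS1 reads cannot be told apart from those of VIM. The serine protease gene HTRA1 fell by 1.68, SMAD6, an inhibitor of BMP signalling, fell by 1.62, and DUSP2 fell by 1.41. XAF1, a member of the interferon-stimulated list above and so part of that pattern, fell by 1.42. RPS10 fell by 1.44 (SE 0.28, adjusted p = 0.0162). Summed with its overlapping model RPS10-NUDT3 it stood at 14.9 ± 3.29 CPM in control and 13.5 ± 1.47 CPM with cadmium. TMPRSS3 and XAF1 without control replicate 1 (adjusted p from 0.0902 to 0.161), XAF1 and RPS10 without cadmium replicate 1 (adjusted p from 0.0759 to 0.276), and XAF1 without cadmium replicate 2 (adjusted p = 0.207) no longer passed. XAF1 moved to -0.62 without control replicate 1.

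The authors' deposited table calls 1981 genes at an adjusted p under 0.05, 983 higher and 998 lower in cadmium. Of these 1854 were also called by edgeR, all 1854 with the same sign. Both come from the same 4 libraries and are not independent.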

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

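Level-dependent scaling, thinning, the crossed block, leaving out read-through models, and the seed-site tests under the replicate block and minus the loess trend were chosen after the data were seen. The counts of 1209 higher and 1046 lower genes stayed within 1.5 times under DESeq2, limma-voom, DESeq2 size factors, no filter, the stricter filter, level-dependent scaling, thinning and without read-through models. Scaling by library size alone gave 682 lower genes. Stricter criteria gave 233 higher and 149 lower at an adjusted p under 0.01, and 80 and 13 with a tested fold of 1.5. With 1 library left out 369 to 1977 were higher and 235 to 1791 lower, lowest without cadmium replicate 1 and highest without control replicate 2, and the cause was not tested. Of 116 named genes that passed, some lost the call with 1 library left out, more without a cadmium than without a control library. Each of these fits kept 3 libraries, so the number of samples does not account for that difference. Without a cadmium library the spread comes from the 2 controls alone. These differed more than the cadmium libraries (chi-square per gene 11.8 against 7.72). Whether this lowered the calls was not tested. Over all alternatives 1541 values of named genes kept direction and side of the threshold and 268 lost the call. SNAI1 kept its direction, from 1.55 to 2.74 with 1 library left out. It missed the threshold at 1.96 against a tested fold of 1.5 (adjusted p = 0.117) and at 1.55 without cadmium replicate 1. Its main edgeR adjusted p of 0.0141 was also above 0.01. The stricter filter of 5 CPM in 2 libraries removed SNAI1, so it was not tested there.

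The replicate numbers did not pair the libraries (correlation of the replicate differences across genes -0.14). With the replicate block 1073 genes were higher and 811 lower, the SNAI1 log2 fold change was 2.08, lists called were 11 higher and 9 lower, and the miR-30 difference was 0.088 (permutation p = 0.0483). Lists that passed camera with the block and not without it were heat shock genes (adjusted p = 0.0465), EMT factors (adjusted p = 0.0496), mesenchymal genes (adjusted p = 0.0294), p53 targets (adjusted p = 0.0353) and histone genes (adjusted p = 0.0465). Of genes named in the report, FN1 (adjusted p = 0.0350) and COL1A1 (adjusted p = 0.0406) passed with the block, and TFRC (adjusted p = 0.0960), MANF (adjusted p = 0.0655), SNAI3 (adjusted p = 0.0831) and XPA (adjusted p = 0.0507) no longer passed. A crossed block gave 1551 higher and 1471 lower.

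Of the 9 lists called higher and 6 called lower, 0 and 0 were called with an estimated correlation and 0 and 0 with fry. The miR-30 difference was 0.057 with 7-mer sites, 0.071 minus the loess trend and 0.048 to 0.13 with 1 library left out, each short of the threshold, and the cause was not tested. Among genes with a mean of at least 5 CPM the miR-30 difference was 0.10 and passed (permutation p = 0.0268). Directions changed for results that did not pass. VIM turned to 0.027 with library size alone, 0.0064 with the stricter filter, 0.064 with level-dependent scaling and 0.070 without control replicate 1, within -0.13 to 0.070. CDH2 ranged from -0.074 to 0.11 with 1 library left out, and was 0.077 with library size alone and 0.12 with level-dependent scaling. List medians where the camera direction turned were, for miR-30 targets, 0.016 with library size alone, -0.042 with no filter and -0.048 with the stricter filter. Level-dependent scaling gave 0.0043 for DNA replication and -0.042 for apoptosis. With 1 library left out medians were -0.14 to 0.38 for heat shock, -0.011 to 0.057 for chaperones, 0.025 to 0.27 for proteases, -0.14 to 0.11 for TGF-beta, -0.13 to 0.18 for miR-30 targets, -0.34 to -0.021 for p53, -0.20 to 0.15 for apoptosis and -0.27 to 0.055 for cytokine genes. The cause was not tested. Pseudocount alternatives were not run, since the files hold counts. Depth limits genes near the floor, such as CDH1, most of all in control replicate 2.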

Other observations

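The families in this paragraph were chosen after their values had been seen, so their direction is not independent evidence. Of 38 NADH dehydrogenase subunit genes (NDUF) 12 fell and 0 rose, with a median log2 fold change of -0.24. Of 23 mitochondrial import genes (TIMM and TOMM) 9 fell and 0 rose, with a median of -0.34. Of 77 mitochondrial ribosomal protein genes 27 fell and 0 rose, with a median of -0.28. Random lists matched on expression had median values of -0.067, -0.048 and -0.050, and 0 of 10000 lay below each family. With level-dependent scaling the medians were -0.18, -0.34 and -0.22, and 6, 10 and 18 genes fell. Of 8 actin and tropomyosin genes 5 fell, with a median of -0.57, against -0.065 for matched lists. Of 21 HNRNP genes 8 fell, with a median of -0.21, against -0.094 for matched lists, 3.76% of which lay below it. With level-dependent scaling 2 HNRNP genes fell and the median was -0.12, and it was -0.14 without cadmium replicate 1. Of 14 tubulin genes 4 rose and 2 fell, with a median of 0.068, against -0.045 for matched lists. The tubulin median turned to -0.042 with level-dependent scaling, to -0.011 without control replicate 1 and to -0.0040 without cadmium replicate 2, and was 0.032 without control replicate 2 and 0.13 with library size alone. With level-dependent scaling 4 tubulin genes rose and 0 fell. These 6 families are all that were examined.

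In the patterns that follow, the tests of GC content and length, of both read-through explanations and of the interferon list were chosen after the result, or part of it, was seen. Low-count genes were higher and abundant genes lower in cadmium, with a median log2 fold change of 0.36 among 1692 genes under 2 CPM and -0.10 among 2021 genes over 128 CPM (Spearman rho across genes, which are not independent replicates, -0.30). Thinning to equal depth left rho at -0.26, which argues against depth as the whole cause. Over the 12499 genes with a 3' UTR rho was -0.33. With GC content and transcript length removed the partial rho over these genes was -0.35, which argues against GC content and length. Uniform background reads may raise low genes, but 378 olfactory receptor genes differed by 0.000772 RPKM, with an upper counting limit of 0.00233, against a median difference of 0.0741 RPKM among genes under 2 CPM. RNA quality, the experiment number and an effect of cadmium were not tested and stay open.

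Of read-through gene models, 8 had at least 20 reads in cadmium and 0 in control, and 0 the opposite. Assignment of shared reads that varies between libraries is a candidate explanation, since 11.25% of 80 such models had at least 30 reads in 1 library and 0 in its group-mate, against 0.0927% of 12941 other genes (1-sided Fisher exact p = 2.17e-15). Summed with 1 neighbour, these 8 models gave log2 ratios of mean CPM from -0.33 (PTCD1 with ATP5J2-PTCD1) to 0.67 (TMEFF1 with MSANTD3-TMEFF1), with a median of -0.065 over 16 sums, 5 of them above 0, or a median of -0.0075 and 8 above 0 with library size alone. A general rise of read-through transcription cannot be told apart from none, since 74 tested models had a median log2 fold change of 0.22 with quartiles of -0.24 and 0.53. Of the 8 models without control reads, SLMO2-ATP5E had 0 and 203 reads in cadmium replicates 1 and 2, and UBE2F-SCLY had 64 and 0. The others had reads in both cadmium libraries, in some unevenly, such as COMMD3-BMI1 with 13 and 181. Cadmium itself stays open as a cause.

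The fall of interferon-stimulated genes leaned on control replicate 1. The median log2 fold change of 21 genes was -0.94 over all libraries, -0.36 without control replicate 1 and -1.33 without control replicate 2. Camera still called the list without control replicate 1 (adjusted p = 0.000314), with the preset correlation. With an estimated correlation over all libraries the adjusted p was 0.551. Whether a single high control may account for the pattern cannot be told apart from an effect of cadmium, because 1 control then remains and the fall lies between the values set for either case.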
